A study of Mus musculus with 8 samples.

How the data were processed

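Poly-A RNA was sequenced from mouse embryonic stem (ES) cells, the self-renewing cells derived from the early embryo. The 8 libraries fall into 4 groups of 2 per the labels: unedited cells (WT), cells made with Cas9 to lack Pcgf3 (Pcgf3KO) or Pcgf5 (Pcgf5KO), and double knockout cells lacking both (DKO). Pcgf3 and Pcgf5 encode RING finger proteins of variant Polycomb repressive complexes, which ubiquitinate a core histone at silent genes. Per the labels' protocols the cells were of strain C57BL/6 and were kept in serum with leukemia inhibitory factor on mitomycin-treated mouse embryonic fibroblasts, so fibroblast RNA can be in each library. Libraries were made with the NEBNext Ultra RNA kit from poly-A selected RNA, per the labels' protocols. That kit does not mark strand, so reads of a gene and of an overlapping gene on the other strand (as at Aire, Col4a1, Otx2 and Igf2) cannot be told apart.

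The deposited tables hold whole-number counts of reads per Ensembl gene, 1 table per library, per the file headers and the values. TopHat2 2.0.12, Cufflinks 2.2.1, HTSeq 0.6.0 and the genome build mm10 are named in the submitters' processing notes, which give no role or order. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. 0 entries named no gene, so none was left out of the library totals. The tables give Ensembl identifiers and positions, and 46488 of the 47069 identifiers were matched to a symbol in the reference annotation (GENCODE release M21). Coordinates are those of the deposited tables (mm10, 1-based).

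The copy of the WT replicate 1 table used here breaks off in the middle of a line and lists 8093 genes, the first 17.2% of the list in the other 7 tables, without Pcgf3 and Pcgf5. Genes not listed were treated as not measured in that library, never as 0. The planned test therefore ran on the genes listed in all 8 libraries and gives levels as counts scaled to library size (CPM, relative to the counts of those genes only). A second test over all genes in the other 7 libraries was added after seeing the data. In it WT is 1 library that is assumed to vary like the libraries of the other groups, and its fold changes against WT have no replicate check on the WT side.

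Differences between groups were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), with group as the only term, TMM normalisation and filterByExpr as the filter on low counts. All groups entered 1 fit, since 2 libraries per group give residual degrees of freedom only when the spread is shared: 4 in the 8-library and 3 in the 7-library fit. The filter left 2702 and 15669 genes, which held 99.92% and 99.93% of the counts. A gene was called at a Benjamini-Hochberg adjusted p of at most 0.05 over all genes tested, and every adjusted p of a gene given below comes from these fits unless another tool is named. The 7 comparisons were each knockout against WT, the DKO against each single knockout, the single knockouts against each other, and the interaction, which is the DKO change minus the sum of the single changes. The ± after a CPM is the SD over 2 libraries, and the ± after a log2 fold change is its standard error.

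The comparisons, the filter, the lists and the rule for genes to name were fixed before the data were examined. The rule takes genes past the threshold with a mean log2 CPM of at least 2 whose libraries in 1 group all lie beyond those of the other: the 10 largest rises and 10 largest falls against WT, and 5 and 5 in the other comparisons (for the interaction without the condition on libraries). Predicted genes were left out. It adds up to 4 members of each list with the smallest p, the 4 most abundant feeder markers, Pcgf3, Pcgf5, Xist and 4 Y-linked genes. Some genes that the rule gives are not reported here, but counts of genes and lists include them.

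The 21 gene lists are naive and core pluripotency, primed epiblast, primitive streak and mesoderm, endoderm, neuroectoderm, trophectoderm, germline and meiosis, Hox, Polycomb-marked developmental regulators, other Polycomb subunits, TGF-beta, Nodal and BMP signalling, Wnt targets, the 2-cell-like state, imprinted genes, p53 targets, feeder fibroblast markers, glycolysis, cholesterol synthesis, the amino acid and ER stress response, the interferon response and proliferation. They were tested in the 7-library fit with camera (limma 3.58.1, through edgeR) at a fixed inter-gene correlation of 0.01, with adjustment over the lists within a comparison. An estimated correlation and fry, which asks if genes of a list move one way without comparison with other genes, were run too. No list passed fry between Pcgf5KO and DKO or Pcgf3KO, and elsewhere some passed camera only. The 7-library fit was used since genes listed in all 8 hold few list members. Of the 2-cell-like list, 18 of 20 members were in the full tables and 0 passed the filter (highest count 6), so it was not tested.

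The total counts per library were 17493194 for WT replicate 2, 19878585 and 18073291 for Pcgf3KO, 17385443 and 12652616 for Pcgf5KO, and 18236113 and 19923964 for DKO. Over the genes listed in all 8 libraries they were 3459002 and 3075594 for WT, 3544487 and 3208001 for Pcgf3KO, 3101611 and 2254855 for Pcgf5KO, and 3245896 and 3558877 for DKO. On counts simulated from the real means at equal spread in all groups, 200 genes, none of low count, were changed. The 8-library DKO against WT comparison found 98% of those changed by a log2 fold change of 1 and 61% of those by 0.5. Of calls, 1.9% were false. The 7-library comparison found 87% and 26%, with 7.4% false. DKO against Pcgf3KO gave 98%, 62% and 3.6% with 8 libraries, and 96%, 53% and 12.4% with 7. With nothing changed, Pcgf5KO against Pcgf3KO gave 0 calls with 8 libraries and 1 with 7. With simulated lists of independent genes in DKO against WT, camera found 5 of 5 moved and 0 of 20 unmoved. Counting intervals are 95% and cover counting error only.

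The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a CPM of at least 1 in at least 2 libraries, a test against a log2 fold change of 0.5 (glmTreat), a fit of only the groups compared, each library left out in turn, and the replicate number as a term. An offset for GC content and transcript length was added after seeing the data, as natural splines of 4 degrees of freedom for each, in the 7-library fit. On simulated counts it raised the number of changed genes found from 193 to 198 of 200, and the false calls from 11 to 17. The labels do not say that replicates come from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical. Comparisons against the same WT libraries share chance values, and 20 sets of unchanged groups were simulated against them.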

Results

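How do mouse ES cells edited to lack Pcgf3, Pcgf5 or both differ in gene expression from unedited cells and from each other? The 7-library test, the only one that covers Pcgf3 and Pcgf5, and the gene families were added after the data were seen.

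Pcgf3 (chromosome 5, 108461232 to 108506976, mm10) had a CPM of 110 in the WT library that covers it, 66.1 and 60.5 in Pcgf3KO, 92.3 and 94.1 in Pcgf5KO, and 86.6 and 67.2 in DKO. Pcgf5 (chromosome 19, 36379067 to 36456192, mm10) had 20.7 in WT, 17.3 and 17.4 in Pcgf3KO, 12.3 and 9.06 in Pcgf5KO, and 13.5 and 13.9 in DKO. Against WT, Pcgf3 fell in Pcgf3KO (log2 fold change −0.79 ± 0.14, adjusted p = 0.021) and Pcgf5 fell in Pcgf5KO (−0.94 ± 0.18, adjusted p = 0.0292). In DKO neither passed the test, with −0.51 ± 0.14 for Pcgf3 (adjusted p = 0.0899) and −0.60 ± 0.18 for Pcgf5 (adjusted p = 0.114). Pcgf3 did not pass in Pcgf5KO (−0.24, adjusted p = 0.397), nor Pcgf5 in Pcgf3KO (−0.26, adjusted p = 0.546). Each was thus lowest in its own single knockout and present in all edited cells. A frameshift made by Cas9 need not lower a transcript, so these levels neither prove nor exclude loss of the proteins.

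**Figure D1:**
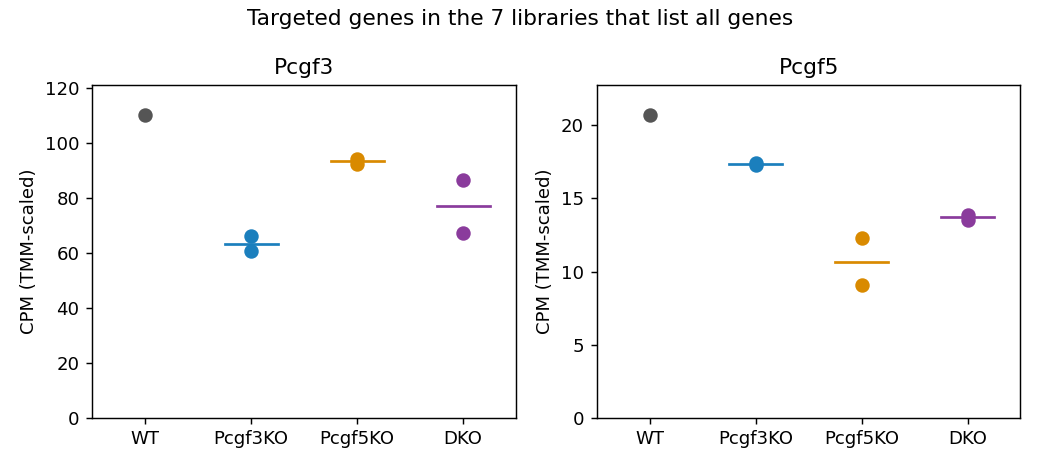
Levels of Pcgf3 and Pcgf5 (y axis, CPM) in each of 7 libraries by group (x axis), with bars at group means. WT is 1 library, at 110 for Pcgf3 and 20.7 for Pcgf5.

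The sex-linked genes check the cell lines. Xist, the RNA that silences an X chromosome in female cells, was between 0.683 and 3.58 CPM in all 7 libraries. The Y-linked genes Kdm5d (14.8 to 22.1), Ddx3y (59.1 to 83.5) and Uty (25.2 to 32.5) were present in each of these 7. Eif2s3y was between 56.8 and 66.8 in 6 libraries and 6.11 in DKO replicate 1. Over the genes listed in all 8 libraries, replicates correlated at 0.991 in WT, 0.994 in Pcgf3KO, 0.992 in Pcgf5KO and 0.985 in DKO, and DKO replicate 2 correlated best with Pcgf3KO replicate 1 (0.989). Between the WT libraries edgeR called 0 of 2702 genes, with 132 at an unadjusted p of at most 0.05. The chi-square per gene between replicates was 6.79 in WT, 4.48 in Pcgf3KO, 1.86 in Pcgf5KO and 21.6 in DKO, so the DKO libraries were the furthest apart.

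Which genes differ between Pcgf3KO and WT? With 8 libraries, Lemd1 rose from 13.6 ± 2.62 to 106 ± 3.2 CPM (log2 fold change 2.96 ± 0.2, adjusted p = 2.54e-05). The noncoding antisense RNA Ptprtos rose from 19.6 ± 0.946 to 94.6 ± 4.67 (2.27 ± 0.16, adjusted p = 2.73e-05). D1Pas1, an autosomal helicase gene, rose from 27.2 ± 2.46 to 90 ± 0.366 (1.73 ± 0.17, adjusted p = 0.000202). C78283 rose from 11.8 ± 0.739 to 49.7 ± 8.84 (2.07 ± 0.23, adjusted p = 0.000384). Among the falls, Csf1, the macrophage growth factor, went from 71 ± 5.01 to 14 ± 1.48 (−2.33 ± 0.22, adjusted p = 0.000163). Bmp1, a procollagen-cleaving protease, went from 179 ± 18.4 to 52.2 ± 0.0616 (−1.77 ± 0.21, adjusted p = 0.000722).

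Also higher were Apol6 (2.60 ± 0.41, adjusted p = 0.0049), Ndufa4l2 (2.09 ± 0.32, adjusted p = 0.00412), Gpat2 (2.04 ± 0.38, adjusted p = 0.0115), Cd79b (1.79, adjusted p = 0.0213) and Ulbp1 (1.73, adjusted p = 0.0254). Also lower were Bcl11b (−2.38 ± 0.59, adjusted p = 0.0414), Asb4 (−2.27 ± 0.44, adjusted p = 0.0143), Acsbg1 (−1.92, adjusted p = 0.0445), Pmp22 (−1.65 ± 0.23, adjusted p = 0.00203), Cyp1b1 (−1.64, adjusted p = 0.0414) and Tnfaip6 (−1.62, adjusted p = 0.045). Tifab had 38 counts in Pcgf3KO and 3 in WT, a ratio of 12.5 (interval 3.97 to 63.4), and Peg13 had 2 and 149, a ratio of 0.0133 (0.00159 to 0.0488). In all, 86 genes were higher and 63 lower of 2702 tested, 30 and 25 of them by more than 2-fold. Without Pcgf3KO replicate 1 the counts were 28 and 12, and without DKO replicate 1 230 and 207. Lemd1, Ptprtos, C78283, D1Pas1, Csf1, Bmp1 and Pmp22 passed whichever library was left out, while 11 of the 20 named genes did not pass without WT replicate 2, with adjusted p up to 0.283.

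With 7 libraries, 170 genes were higher and 200 lower of 15669, and 59 of the 64 of these calls that the 8-library test covers were called there too. Gstp2, a glutathione transferase gene, rose from 1.48 to 14.4 ± 1.4 CPM (3.28 ± 0.27, adjusted p = 0.000877), with paralogs that may share its reads. Also higher were Slfn9 (3.86 ± 0.56, adjusted p = 0.00945), As3mt (3.20 ± 0.36, adjusted p = 0.00284), Arl14epl (2.53 ± 0.38, adjusted p = 0.011), Aire (2.40 ± 0.42, adjusted p = 0.021), Slc4a5 (2.39 ± 0.25, adjusted p = 0.00198) and Myo1g (2.18 ± 0.26, adjusted p = 0.0041). Efhc2, an X-linked EF-hand gene, fell from 21.6 to 2.27 ± 0.207 (−3.24 ± 0.21, adjusted p = 0.000352), and Vgf from 44.9 to 11.4 ± 0.538 (−1.98 ± 0.19, adjusted p = 0.0013). Hand1 (−2.30 ± 0.47, adjusted p = 0.0378), Thbs1 (−1.80 ± 0.16, adjusted p = 0.000979), Hmga2 (−1.78 ± 0.26, adjusted p = 0.00984), Trpa1 (−1.78) and Dcaf12l1 (−1.73 ± 0.12, adjusted p = 0.000486) were lower. Without 1 of the Pcgf3KO replicates 7 or 8 of the 20 did not pass, among them Aire and Hand1 (adjusted p up to 0.265). The counts were 27 and 19 without Pcgf3KO replicate 1, and 1588 and 1579 without DKO replicate 1.

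Do the changes in Pcgf3KO run in gene groups? At the fixed correlation they did in 14 of the 20 lists tested, with falls the most frequent, and at an estimated one in 0 by camera (lowest adjusted p = 0.0538). Of 19 p53 target genes, 0 were higher, 7 lower and 12 did not pass (0 and 12 adjusted over the list alone). Their median was −0.48 (camera adjusted p = 4.29e-16, adjusted p = 0.0538 with an estimated correlation). Plk2 (−1.45 ± 0.13, adjusted p = 0.000979), Perp (−1.19 ± 0.14, adjusted p = 0.00356) and Pmaip1 (−0.93 ± 0.1, adjusted p = 0.00198) led it. Of 24 pluripotency genes 5 were higher and 0 lower (10 and 0 adjusted over the list alone). Led by Dppa5a (0.74 ± 0.11, adjusted p = 0.0106) and Tcl1 (1.34 ± 0.2, adjusted p = 0.0119), the list had a median of 0.21 (adjusted p = 2.14e-07, adjusted p = 0.0699 with an estimated correlation). Of 26 germline genes 4 were higher and 0 lower (9 and 0 adjusted over the list alone). Led by the meiosis genes Tex14 (0.97 ± 0.14, adjusted p = 0.00905), Stag3 (1.08 ± 0.18, adjusted p = 0.0149) and Smc1b (2.82 ± 0.48, adjusted p = 0.0187), the list had a median of 0.56 (adjusted p = 3.9e-06, adjusted p = 0.0894 with an estimated correlation). Of 19 glycolysis genes 4 were higher and 1 lower (9 and 2 adjusted over the list alone). The median was 0.25 (adjusted p = 0.00015, adjusted p = 0.278 with an estimated correlation), and the 1 lower was Pgk1 (−0.72 ± 0.08, adjusted p = 0.00198).

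The lineage lists fell in Pcgf3KO. Of 15 endoderm genes 4 were lower (6 adjusted over the list alone). Led by the basement membrane collagen gene Col4a1 (−1.58 ± 0.13, adjusted p = 0.000877), Col4a2 (−1.82 ± 0.2, adjusted p = 0.0022) and Dab2 (−1.67), the list had a median of −0.56 (adjusted p = 4.26e-10, adjusted p = 0.123 with an estimated correlation). Of 16 neuroectoderm genes 4 were lower (8 adjusted over the list alone). Led by Olig2 (−0.92 ± 0.11, adjusted p = 0.00308), the list had a median of −0.77 (adjusted p = 3.43e-10, adjusted p = 0.0699 with an estimated correlation). Of 20 primitive streak genes 3 were lower (4 adjusted over the list alone). Led by Tbx20 (−1.45 ± 0.18, adjusted p = 0.00488) and Kdr (−1.35, adjusted p = 0.012), the list had a median of −0.32 (adjusted p = 0.00128, adjusted p = 0.282 with an estimated correlation). Of 11 trophectoderm genes 3 were lower (2 higher and 4 lower adjusted over the list alone). Led by the keratins Krt18 (−1.42, adjusted p = 0.0157) and Krt8 (−1.15, adjusted p = 0.0239), the list had a median of −0.39 (adjusted p = 0.00743, adjusted p = 0.464 with an estimated correlation). Of 23 feeder fibroblast markers 6 were lower (16 adjusted over the list alone). Their median was −0.81 (adjusted p = 1.4e-13, adjusted p = 0.0699 with an estimated correlation), and the lower ones included Col1a1 (−1.46 ± 0.21, adjusted p = 0.00984) and Mmp2 (−0.77, adjusted p = 0.0183). The most abundant markers Tagln (−0.54, adjusted p = 0.0622), Col5a1 (−0.66, adjusted p = 0.0587) and Thy1 (−0.56, adjusted p = 0.264) did not pass. Col4a1 and Col4a2 thus fell beside markers of the fibroblasts, Col1a1 among them.

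Of 22 TGF-beta, Nodal and BMP genes 4 were lower (4 adjusted over the list alone), with a median of −0.28 (adjusted p = 5.48e-06, adjusted p = 0.0894 with an estimated correlation). Among them was Lefty2, a Nodal antagonist (−1.06 ± 0.09, adjusted p = 0.000979). Of 32 imprinted genes 5 were lower (8 adjusted over the list alone). Led by the growth factor gene Igf2 (−1.72 ± 0.21, adjusted p = 0.00485), the list had a median of −0.075 (adjusted p = 0.00794, adjusted p = 0.123 with an estimated correlation). The last 3 lists that fell had 0 members called in edgeR, over all genes and adjusted over the list alone. Polycomb-marked regulators (21 genes) had a median of −1.21 (adjusted p = 5.87e-05, adjusted p = 0.18 with an estimated correlation), with Msx2 at −1.39 ± 0.42 (adjusted p = 0.132). Cholesterol synthesis (22 genes) had −0.24 (adjusted p = 0.000271, adjusted p = 0.439 with an estimated correlation), with Nsdhl at −0.45 (adjusted p = 0.125). Hox (6 genes) had −1.14 (adjusted p = 0.026, adjusted p = 0.278 with an estimated correlation). The Hox result did not pass without DKO replicate 1 (adjusted p = 0.0936) or 2 (0.0812). The interferon response (median 0.16, adjusted p = 0.0535) did not pass, though Ddx58 rose (0.56 ± 0.11, adjusted p = 0.0327). Nor did the other Polycomb subunits (0.038, adjusted p = 0.167), where Phf19 (0.81 ± 0.1, adjusted p = 0.00507) and Jarid2 (0.54, adjusted p = 0.0224) rose. The amino acid and ER stress response (−0.052, adjusted p = 0.254), with Atf3 lower (−1.40, adjusted p = 0.0303), primed epiblast (−0.13, mean 0.049, adjusted p = 0.254), proliferation (0.018, adjusted p = 0.441) and Wnt targets (−0.048, adjusted p = 0.471) did not pass. The interferon list passed without Pcgf3KO replicate 2 (0.0372), DKO replicate 1 (0.046) or 2 (0.0438).

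**Figure D2:**
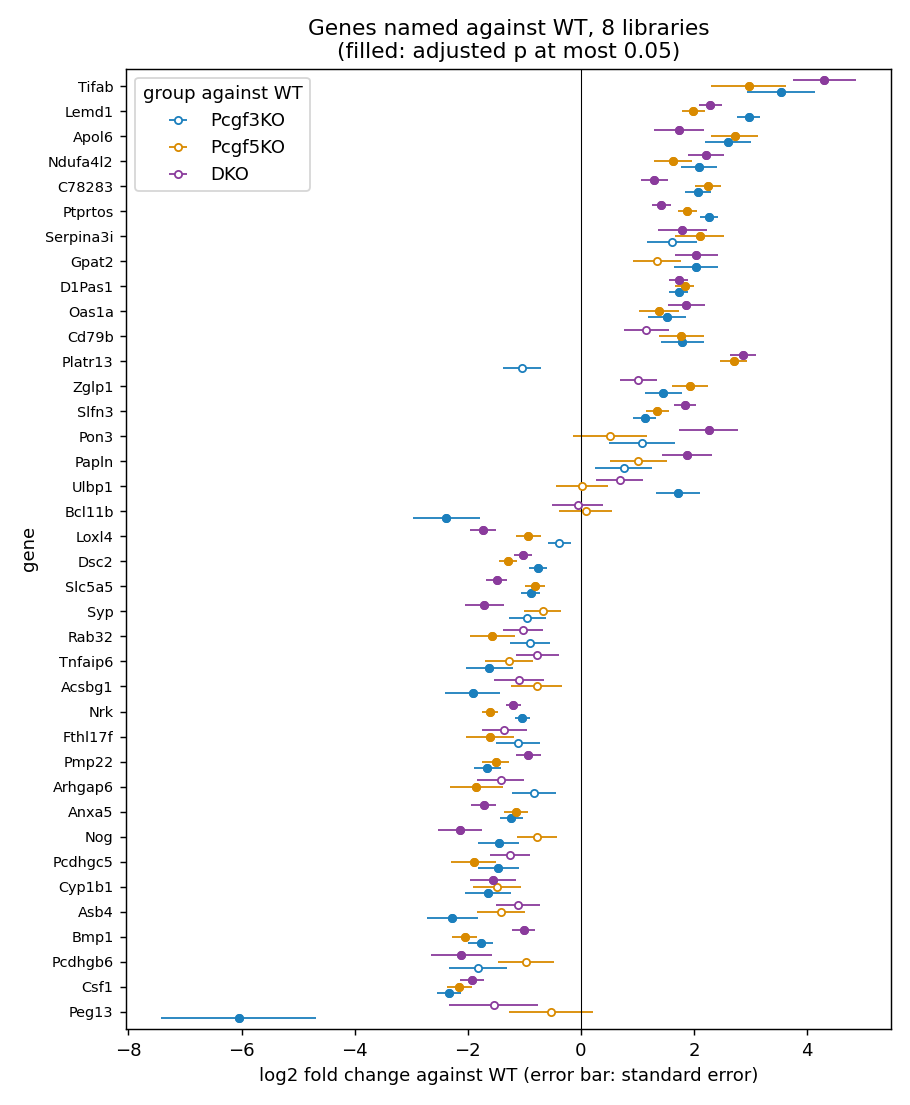
Log2 fold change against WT ± standard error (x axis) of genes named against WT (y axis) in the 3 knockout groups with 8 libraries, filled where adjusted p is at most 0.05. Lemd1 is at 2.96 in Pcgf3KO, 1.99 in Pcgf5KO and 2.29 in DKO.

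Which genes differ between Pcgf5KO and WT? With 8 libraries, Platr13, a noncoding RNA named for its tie to pluripotency, rose from 6.82 ± 0.349 to 44.7 ± 7.8 CPM (2.70 ± 0.24, adjusted p = 0.000134). C78283 (2.25 ± 0.23, adjusted p = 0.000203), Lemd1 (1.99 ± 0.21, adjusted p = 0.00023), Ptprtos (1.88 ± 0.17, adjusted p = 0.000134) and D1Pas1 (1.84 ± 0.17, adjusted p = 0.000142) rose as in Pcgf3KO, to 56.2 ± 1.1, 53.8 ± 1.93, 72.5 ± 4.35 and 97 ± 0.891. Csf1 fell to 15.9 ± 0.481 (−2.15 ± 0.22, adjusted p = 0.000203) and Bmp1 to 43.1 ± 1.77 (−2.05 ± 0.22, adjusted p = 0.000321). Nrk, an X-linked kinase gene, fell from 196 ± 27.3 to 64.8 ± 6.21 (−1.60 ± 0.14, adjusted p = 0.000134), and the desmosome gene Dsc2 from 61.1 to 25.1 (−1.29 ± 0.17, adjusted p = 0.00113). Apol6 (2.72 ± 0.42, adjusted p = 0.00357), Zglp1 (1.94 ± 0.32, adjusted p = 0.00467), Serpina3i (2.10, adjusted p = 0.0182) and Cd79b (1.78, adjusted p = 0.022) were also higher. Pmp22 (−1.51, adjusted p = 0.00411), Pcdhgc5 (−1.89, adjusted p = 0.0183), Arhgap6 (−1.85, adjusted p = 0.0339), Rab32 (−1.56, adjusted p = 0.0358) and Fthl17f (−1.61, adjusted p = 0.0411) were also lower. Tifab had 20 counts in Pcgf5KO and 3 in WT, a ratio of 8.44 (interval 2.5 to 44.4). In all, 117 genes were higher and 116 lower, 25 and 27 by more than 2-fold. Without Pcgf5KO replicate 1 the counts were 20 and 13 and 8 of the 20 named genes did not pass (adjusted p up to 0.337), nor did Zglp1 without Pcgf5KO replicate 2 (0.0798) or WT replicate 2 (0.0547), while without DKO replicate 1 they were 334 and 295.

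With 7 libraries, 205 genes were higher and 263 lower, and 83 of 86 of these calls held in the 8-library test. Smtnl1 rose from 1.14 to 9.85 ± 0.707 CPM (3.10 ± 0.28, adjusted p = 0.00116) and Serpinf1 from 6.15 to 24.4 ± 1.09 (1.99 ± 0.19, adjusted p = 0.00122). Igf2 fell from 268 to 68.4 ± 1.98 (−1.97 ± 0.22, adjusted p = 0.00258), Dsp from 70 to 15.8 ± 0.32 (−2.15 ± 0.18, adjusted p = 0.000997), and Hand1, a heart and placenta transcription factor gene, from 45.8 to 6.08 ± 1.28 (−2.89 ± 0.49, adjusted p = 0.0196). Slfn9 (3.32), As3mt (2.99), Gstp2 (2.58 ± 0.28, adjusted p = 0.00229), Myo1g (2.16) and Aire (1.95) were higher. Vgf (−2.31 ± 0.2, adjusted p = 0.000997), Col4a2 (−1.92), Cryab (−1.79), Myof (−1.77 ± 0.17, adjusted p = 0.00147) and Hmga2 (−1.76) were lower. Without Pcgf5KO replicate 1 11 of the 20 did not pass (adjusted p up to 0.234), and without a Pcgf3KO replicate Aire did not (0.0979 and 0.0986). The counts then were 18 and 19 without Pcgf5KO replicate 1, and 2073 and 2046 without DKO replicate 1.

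In Pcgf5KO 13 of the 20 lists passed. Of 19 p53 targets 7 were lower and 0 higher (9 adjusted over the list alone). Their median was −0.44 (adjusted p = 1.23e-10, adjusted p = 0.106 with an estimated correlation), again with Plk2 (−1.35 ± 0.13, adjusted p = 0.00141) and Perp (−1.23 ± 0.14, adjusted p = 0.0031). Of 24 pluripotency genes 6 were higher (9 higher and 1 lower adjusted over the list alone). Led by Dppa5a (0.82 ± 0.11, adjusted p = 0.00685) and Nr5a2 (0.68 ± 0.11, adjusted p = 0.0141), the list had a median of 0.27 (adjusted p = 2.19e-05, adjusted p = 0.162 with an estimated correlation). Of 19 glycolysis genes 5 were higher and 1 lower (12 and 1 adjusted over the list alone). With Tpi1 higher (0.63 ± 0.09, adjusted p = 0.00703) and the glucose transporter gene Slc2a3 lower (−0.88 ± 0.08, adjusted p = 0.00117), the list had a median of 0.37 (adjusted p = 1.72e-06, adjusted p = 0.218 with an estimated correlation). The interferon list rose (median 0.51, adjusted p = 0.00648, adjusted p = 0.162 with an estimated correlation). Ddx58, an RNA sensor gene, was its 1 call of 11 (1 adjusted over the list alone), at 0.67 ± 0.11 (adjusted p = 0.0158). Of 11 trophectoderm genes 4 were lower (1 higher and 8 lower adjusted over the list alone). Led by Krt8 (−1.44 ± 0.21, adjusted p = 0.00949) and Krt18 (−1.53 ± 0.23, adjusted p = 0.0119), the list had a median of −0.97 (adjusted p = 3.27e-07, adjusted p = 0.271 with an estimated correlation). Of 15 endoderm genes 4 were lower (5 adjusted over the list alone). Led by Col4a1 (−1.49 ± 0.13, adjusted p = 0.00115), the list had a median of −0.45 (adjusted p = 4.62e-07, adjusted p = 0.191 with an estimated correlation).

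Of the feeder markers in Pcgf5KO 1 of 23 was lower (8 adjusted over the list alone). Their median was −0.54 (adjusted p = 8.76e-06, adjusted p = 0.162 with an estimated correlation), with Col1a1 at −1.09 ± 0.22 (adjusted p = 0.0317). Mmp2 (−0.54, adjusted p = 0.0682), Tagln (−0.34, adjusted p = 0.186), Col5a1 (−0.34, adjusted p = 0.267) and Thy1 (−0.22, adjusted p = 0.643) did not pass. Neuroectoderm fell, with 3 of 16 lower (6 adjusted over the list alone) and a median of −0.53 (adjusted p = 0.000397, adjusted p = 0.162 with an estimated correlation). TGF-beta, Nodal and BMP signalling fell, with 4 of 22 lower and 1 higher (7 and 1 adjusted over the list alone) and a median of −0.32 (adjusted p = 0.000705, adjusted p = 0.162 with an estimated correlation). Its members Nodal (0.78 ± 0.13, adjusted p = 0.0189) and Ccn2 (−0.79 ± 0.12, adjusted p = 0.0136) went apart. Of 32 imprinted genes 5 were lower (6 adjusted over the list alone), Peg10 among them (−0.66 ± 0.09, adjusted p = 0.00752), with a median of −0.14 (adjusted p = 0.00477, adjusted p = 0.162 with an estimated correlation). Primitive streak fell, with 2 of 20 lower (2 adjusted over the list alone), Tbx20 among them (−1.44 ± 0.19, adjusted p = 0.00532), and a median of −0.27 (adjusted p = 0.0164, adjusted p = 0.409 with an estimated correlation). Cholesterol synthesis fell, with Idi1 (−0.60 ± 0.11, adjusted p = 0.0249) as the 1 lower of 22 (7 adjusted over the list alone) and a median of −0.26 (adjusted p = 2.19e-05, adjusted p = 0.409 with an estimated correlation). Polycomb-marked regulators fell with 0 of 21 called (1 and 1 adjusted over the list alone), Msx2 at −1.90 ± 0.45 and a median of −0.98 (adjusted p = 0.000705, 0.218 with an estimated correlation). Their 1 member tested with 8 libraries was called higher (0.64). The primitive streak list did not pass without Pcgf5KO replicate 1. Wnt targets did not pass as a list (0.008, adjusted p = 0.119), while Notum (1.29 ± 0.24, adjusted p = 0.0281) and Lef1 (2.58 ± 0.56, adjusted p = 0.0429) rose. Hox (−0.87, adjusted p = 0.0717), proliferation (0.11, adjusted p = 0.114), amino acid and ER stress response (−0.067, adjusted p = 0.237), germline (0.14, adjusted p = 0.462) and other Polycomb subunits (0.013, mean −0.011, adjusted p = 0.53) did not pass. Primed epiblast did not either (−0.01, mean 0.241, adjusted p = 0.566), and in it Cdh2 fell (−1.25 ± 0.16, adjusted p = 0.00451) and Zic2 rose (0.94 ± 0.15, adjusted p = 0.015). The Hox list passed without Pcgf3KO replicate 1 (0.046) or 2 (0.0448) and without Pcgf5KO replicate 2 (0.0193).

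Which genes differ between DKO and WT? With 8 libraries, Platr13 rose to 49.8 ± 0.416 CPM in DKO (2.86 ± 0.23, adjusted p = 0.000106) and Lemd1 to 66.2 ± 13.4 (2.29 ± 0.2, adjusted p = 0.000164). Slfn3, a Schlafen gene with close paralogs, rose from 14.9 ± 1.98 to 53.4 ± 3.64 (1.84 ± 0.19, adjusted p = 0.000411), and the antiviral gene Oas1a from 6.5 ± 3.53 to 23.3 ± 0.983 (1.86 ± 0.33, adjusted p = 0.00621). Nog, whose product blocks BMP signals, fell from 13.5 to 3.04 ± 0.341 (−2.14 ± 0.39, adjusted p = 0.00736), and Slc5a5 from 72.4 ± 3.85 to 25.8 ± 0.965 (−1.49 ± 0.18, adjusted p = 0.00091). Csf1 fell to 18.6 ± 5.28 (−1.92 ± 0.21, adjusted p = 0.000484). Also higher were Ndufa4l2 (2.22 ± 0.32, adjusted p = 0.00199), Gpat2 (2.04 ± 0.38, adjusted p = 0.00856), Pon3 (2.26 ± 0.52, adjusted p = 0.0238), Papln (1.88, adjusted p = 0.0262) and Serpina3i (1.80, adjusted p = 0.0293). Also lower were Anxa5 (−1.72 ± 0.22, adjusted p = 0.000943), Loxl4 (−1.73 ± 0.23, adjusted p = 0.00106), Syp (−1.71, adjusted p = 0.0129), Pcdhgb6 (−2.11, adjusted p = 0.0344) and Cyp1b1 (−1.56, adjusted p = 0.0384). Tifab had 67 counts in DKO and 3 in WT, a ratio of 21.3 (interval 6.98 to 106). In all, 119 genes were higher and 100 lower, 49 and 31 by more than 2-fold. Without WT replicate 1 they were 29 and 31, and without DKO replicate 2 385 and 379; 8 of the 20 named genes did not pass without WT replicate 2 (adjusted p up to 0.179) and 7, with Oas1a (0.0612), without WT replicate 1 (up to 0.245).

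With 7 libraries, 209 genes were higher and 296 lower, and 77 of 81 of these calls held with 8 libraries. The homeobox gene Rhox5 rose from 13.3 to 70.3 ± 9.83 CPM (2.40 ± 0.19, adjusted p = 0.000578) and Otx2, a head and epiblast transcription factor gene, from 1.82 to 11.8 ± 2.81 (2.69 ± 0.3, adjusted p = 0.00229). Acta2, smooth muscle actin, fell from 11.1 to 0.861 ± 0.249 (−3.67 ± 0.27, adjusted p = 0.000563). Krt8 (−2.17 ± 0.21, adjusted p = 0.00119) and its partner Krt18 (−1.97 ± 0.23, adjusted p = 0.00288) fell from 418 to 92.6 ± 32.3 and from 278 to 70.7 ± 28. Thbs1 (−2.46 ± 0.16, adjusted p = 0.000476), Efhc2 (−3.28 ± 0.21, adjusted p = 0.000476), Vgf (−2.36 ± 0.19, adjusted p = 0.000578), Dsp (−2.32 ± 0.18, adjusted p = 0.000578), Cryab (−2.09), Has2 (−1.92) and Anxa5 (−1.88) were lower. Slfn9 (4.31 ± 0.55, adjusted p = 0.00387), Aire (3.05), As3mt (2.92), Smtnl1 (2.86), Slc4a5 (2.64 ± 0.25, adjusted p = 0.000993), Arl14epl (2.53) and Mcf2 (2.11, adjusted p = 0.0202) were higher, and of the 20 only Mcf2 did not pass with a library left out (adjusted p from 0.0512 to 0.0547). The number of calls moved all the same, to 68 and 99 without Pcgf5KO replicate 1 and to 2644 and 2735 without DKO replicate 2.

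Of the 20 lists 13 passed in DKO. Of 16 neuroectoderm genes 5 were lower (9 adjusted over the list alone). Led by Neurod1 (−1.13 ± 0.13, adjusted p = 0.00288), the list had a median of −0.80 (adjusted p = 4.53e-09, adjusted p = 0.158 with an estimated correlation). Of 23 feeder markers 6 were lower (2 higher and 10 lower adjusted over the list alone), with a median of −0.68 (adjusted p = 1.56e-08, adjusted p = 0.158 with an estimated correlation). Tagln (−1.58 ± 0.13, adjusted p = 0.000578) and Col1a1 (−1.40 ± 0.21, adjusted p = 0.0098) fell beside Acta2. In contrast Col5a1 (−0.05, adjusted p = 0.879), Mmp2 (−0.21, adjusted p = 0.421) and Thy1 (0.49, adjusted p = 0.27) did not pass. Of 11 trophectoderm genes 4 were lower (5 adjusted over the list alone), with a median of −0.81 (adjusted p = 2.44e-07, adjusted p = 0.267 with an estimated correlation). Endoderm fell with 3 of 15 lower (6 adjusted over the list alone) and a median of −0.37 (adjusted p = 1.2e-05, adjusted p = 0.216 with an estimated correlation). Primitive streak fell with 2 of 20 lower (2 adjusted over the list alone) and a median of −0.30 (adjusted p = 0.00495, adjusted p = 0.327 with an estimated correlation). Col4a1 (−0.91 ± 0.13, adjusted p = 0.00717), Tbx20 (−1.54 ± 0.18, adjusted p = 0.00288) and Kdr (−1.51 ± 0.21, adjusted p = 0.00563) were among them. Of 24 pluripotency genes 5 were higher and 0 lower (8 and 1 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.00135, adjusted p = 0.159 with an estimated correlation). Tfcp2l1 (0.77 ± 0.09, adjusted p = 0.00335), Klf4 (1.46 ± 0.23, adjusted p = 0.0114) and Tbx3 (1.95 ± 0.36, adjusted p = 0.0227), transcription factor genes of the naive state, had the smallest p. Of 26 germline genes 3 were higher (8 adjusted over the list alone). Led by Smc1b (2.50 ± 0.49, adjusted p = 0.0291), the list had a median of 0.20 (adjusted p = 0.00473, adjusted p = 0.184 with an estimated correlation). The interferon list rose with 1 call of 11 (2 adjusted over the list alone) and a median of 0.38 (adjusted p = 0.00402, adjusted p = 0.159 with an estimated correlation). The call was Oas1a at 1.37 ± 0.3 (adjusted p = 0.0422).

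The p53 targets fell in DKO too, with 2 of 19 lower (3 adjusted over the list alone) and a median of −0.24 (adjusted p = 0.000246, adjusted p = 0.158 with an estimated correlation). The 2 were Perp at −1.55 ± 0.14 (adjusted p = 0.00087) and Plk2 at −1 ± 0.13 (adjusted p = 0.00388). TGF-beta, Nodal and BMP signalling fell with 4 of 22 lower (4 adjusted over the list alone) and a median of −0.25 (adjusted p = 0.000457, adjusted p = 0.159 with an estimated correlation). Polycomb-marked regulators fell with 1 of 21 lower (4 adjusted over the list alone) and a median of −0.74 (adjusted p = 0.000915, adjusted p = 0.227 with an estimated correlation). The amino acid and ER stress response fell with 2 of 22 lower (1 higher and 6 lower adjusted over the list alone) and a median of −0.17 (adjusted p = 0.000915, adjusted p = 0.327 with an estimated correlation), and Atf4, its transcription factor, was at −0.55 ± 0.1 (adjusted p = 0.0235). The imprinted list fell in the test and mean (−0.088) but had a median of 0.049 (adjusted p = 0.0207, adjusted p = 0.184 with an estimated correlation). In it 5 of 32 were lower (7 adjusted over the list alone), with Grb10 at −1.14 ± 0.13 (adjusted p = 0.00229). The lists that did not pass without DKO replicate 1 were Polycomb-marked and amino acid response (adjusted p = 0.0576 each) and primitive streak (0.248), and germline did not without DKO replicate 2 (0.229). The other Polycomb subunits did not pass (0.095, adjusted p = 0.0741), though Suz12, a PRC2 gene, rose (0.76 ± 0.12, adjusted p = 0.0131). Primed epiblast did not pass (−0.041, mean 0.311, adjusted p = 0.563), while in it Zic2 rose (1.42 ± 0.15, adjusted p = 0.00201) and Cdh2 fell (−1.28 ± 0.15, adjusted p = 0.00304). Cholesterol synthesis (−0.10, adjusted p = 0.0707), glycolysis (0.18, adjusted p = 0.105), Hox (−0.013, adjusted p = 0.822), Wnt targets (0.025, adjusted p = 0.945) and proliferation (0.04, adjusted p = 0.945) did not pass. Without DKO replicate 2 cholesterol synthesis (0.000662) and the Polycomb subunits (0.0265) passed, and without DKO replicate 1 glycolysis did (0.00226).

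**Figure D3:**
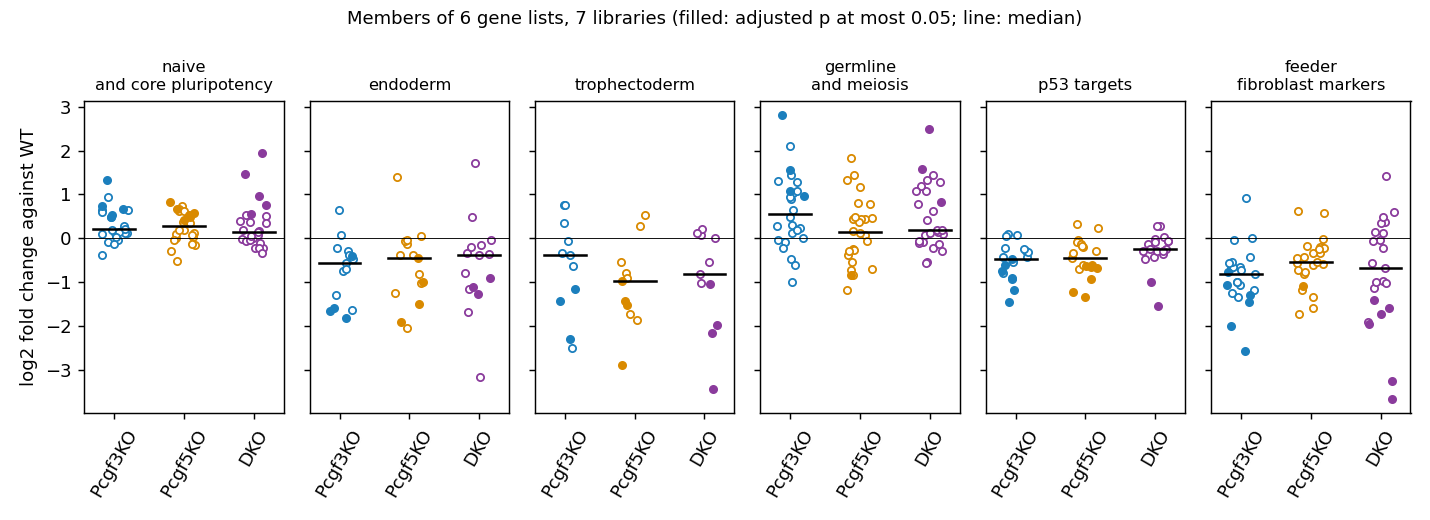
Log2 fold change against WT (y axis) of members of 6 gene lists (panels) in 3 knockout groups (x axis) with 7 libraries. Filled means adjusted p of at most 0.05, and lines mark medians. The p53 targets have medians of −0.48 in Pcgf3KO, −0.44 in Pcgf5KO and −0.24 in DKO.

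Do the 3 groups share their changes against WT? Lemd1 and Csf1 were called in all 3, and with 8 libraries 38 genes were higher and 29 lower in all 3 (65 and 95 with 7). Pcgf3KO and Pcgf5KO shared 62 higher and 40 lower genes, where 3.7 and 2.7 are expected from independent lists, Pcgf3KO and DKO 51 and 34 (3.8 and 2.3), and Pcgf5KO and DKO 50 and 45 (5.2 and 4.3). With 8 libraries 0 genes were called in opposite directions in edgeR, and with 7 libraries 1 was, between Pcgf3KO and Pcgf5KO. The 8-library fold changes correlated at 0.73, 0.64 and 0.61, against 0.47, 0.5 and 0.49 in simulated unchanged groups with the same WT libraries. With 7 libraries they did at 0.78, 0.73 and 0.68 against 0.7, 0.72 and 0.7, and the pairs with DKO did not exceed the highest simulated values of 0.74 and 0.71. The share of genes with the same sign was 76.1%, 69.9% and 64.8% against 66.3%, 66.7% and 66.4% with 8 libraries, and 78.8%, 72.4% and 67% against 73.1%, 73.6% and 73.1% with 7. The 8-library covariance was 0.169, 0.163 and 0.153 against 0.0377, 0.0383 and 0.0391. With no change simulated, few calls could be shared (at most 1). The 2 WT libraries were too few to split, so part of the shared change may come from them.

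Which genes differ between the knockouts? Platr13 was at 3.31 ± 0.674 CPM in Pcgf3KO and was higher in DKO (3.90 ± 0.26, adjusted p = 2.91e-05) and in Pcgf5KO (3.74 ± 0.27, adjusted p = 6.02e-05), whichever library was left out. In DKO against Pcgf3KO, Afap1 (0.77 ± 0.12), Unc5b (0.56 ± 0.1) and the p53 target Trp53inp1 (0.56 ± 0.1) were higher, and Loxl4 (−1.34 ± 0.23), Ptprn (−0.87 ± 0.15), Ptprtos (−0.85 ± 0.14), AU015836 (−0.71 ± 0.13) and Nrp2 (−0.68 ± 0.12) lower, each with adjusted p = 0.0394. These 8 did not pass without either of the Pcgf3KO replicates (adjusted p up to 0.388), and the counts of 4 higher and 10 lower became 291 and 355 without DKO replicate 2. With 7 libraries 115 were higher and 157 lower, of which 14 of the 29 that the 8-library test covers held there. Rhox5 (2.07 ± 0.14, adjusted p = 0.000541), Platr15 (1.98 ± 0.21, adjusted p = 0.00328), Pcdh19 (1.95 ± 0.19, adjusted p = 0.00313), Smtnl1 (1.81) and Zfp990 (1.61 ± 0.14, adjusted p = 0.0027) were higher. Acta2 (−2.61 ± 0.25, adjusted p = 0.00313), the calcium-binding gene S100a6 (−1.78 ± 0.16, adjusted p = 0.0027; 72.8 to 21.2 CPM), Gstp2 (−1.71), Msln (−1.56) and Igf2bp3 (−1.44, adjusted p = 0.0134) were lower. Of these 10, 7 did not pass without Pcgf3KO replicate 2 (adjusted p up to 0.142), when 4 and 3 genes were called, against 2711 and 2860 without DKO replicate 2.

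Of the lists, 5 passed in DKO against Pcgf3KO. The p53 targets were higher, with 3 of 19 called (9 higher and 1 lower adjusted over the list alone). Pmaip1 (0.77 ± 0.08, adjusted p = 0.00328) led the list. Its median was 0.24 (adjusted p = 1.45e-05, 0.251 with an estimated correlation, 0.0176 by fry). Of 13 primed epiblast genes 3 were higher and 1 lower (6 and 2 adjusted over the list alone). Led by Zic2 (0.86 ± 0.11, adjusted p = 0.00897) and Otx2 (1.51 ± 0.2, adjusted p = 0.00978), the list had a median of 0.23 (adjusted p = 0.0318, adjusted p = 0.632 with an estimated correlation). Trophectoderm was lower, with Krt8 (−1.02 ± 0.18, adjusted p = 0.0287) among 2 lower of 11 (1 higher and 5 lower adjusted over the list alone) and a median of −0.66 (adjusted p = 0.00142, adjusted p = 0.694 with an estimated correlation). The amino acid and ER stress response was lower with 0 of 22 called in edgeR (1 higher adjusted over the list alone). Its median was −0.21 (adjusted p = 0.0109, 0.694 with an estimated correlation). Glycolysis was lower with 1 higher and 2 lower of 19 (1 and 7 adjusted over the list alone) and a median of −0.11 (adjusted p = 0.0318, adjusted p = 0.699 with an estimated correlation), although its member Pgk1 was higher (0.96 ± 0.06, adjusted p = 0.000541). None of the last 3 passed without DKO replicate 1 (adjusted p = 0.835, 0.435 and 0.156). Without Pcgf3KO replicate 2 primed epiblast and glycolysis did not pass (0.076 each). Among the feeder markers Fbln2 (1.27 ± 0.17, adjusted p = 0.00889), Thy1 (1.05, adjusted p = 0.0265), Col5a1 (0.61, adjusted p = 0.0483) and Mmp2 (0.57, adjusted p = 0.04) were higher and Tagln lower (−1.04, adjusted p = 0.00328), and the list did not pass (0.23, adjusted p = 0.23). Median and mean differed in sign for neuroectoderm (−0.138 and 0.33), primitive streak (−0.019 and 0.218) and proliferation (0.005 and −0.033).

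In DKO against Pcgf5KO with 8 libraries, Tnc, an extracellular matrix gene, was lower (11.6 to 1.15 CPM, −3.29 ± 0.48, adjusted p = 0.0219), as were Pax6 (−1.47 ± 0.33, adjusted p = 0.0472), Serpina3m (−1.12), Cbr3 (−0.97 ± 0.21) and C78283 (−0.95, adjusted p = 0.0465 for these 3). Kank4 (0.91 ± 0.17, adjusted p = 0.0341), Drp2 (1.98 ± 0.44, adjusted p = 0.0472), Bmp1 (1.05 ± 0.23, adjusted p = 0.0472), Klf15 (0.90 ± 0.19, adjusted p = 0.0465) and Gabbr1 (0.89 ± 0.2, adjusted p = 0.0489) were higher. In all 33 were higher and 31 lower, but without a Pcgf5KO replicate 0 and 0 in edgeR, where 677 genes had an unadjusted p of at most 0.05 with all libraries and DESeq2 called 102 and 113. With 7 libraries 156 were higher and 201 lower, and 42 of 46 of these calls held with 8. Rhox5 (2.12 ± 0.15, adjusted p = 0.000702), Sema5a (1.65 ± 0.14, adjusted p = 0.00236), Pcdh19 (1.5 ± 0.19, adjusted p = 0.0112), Otx2 (1.36 ± 0.21, adjusted p = 0.0211) and Hand1 (2.34 ± 0.44, adjusted p = 0.0373) were higher. Acta2 (−3.25 ± 0.25, adjusted p = 0.000825), Efhc2 (−2.66 ± 0.19, adjusted p = 0.000702), Tagln (−1.24 ± 0.11, adjusted p = 0.00236), Igf2bp3 (−1.86, adjusted p = 0.0112) and Tmem88 (−1.28) were lower. Of these 10, 7 did not pass without a Pcgf5KO replicate (adjusted p up to 0.376), and Rhox5, Acta2 and Efhc2 always did. Without Pcgf5KO replicate 1 the counts were 1 and 2, and without DKO replicate 2 3233 and 3350.

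In DKO against Pcgf5KO 6 lists passed camera only. Glycolysis was lower, with 5 of 19 lower (2 higher and 10 lower adjusted over the list alone), Slc2a1 among them (−0.55 ± 0.08, adjusted p = 0.0157), and a median of −0.20 (adjusted p = 0.00193, adjusted p = 0.791 with an estimated correlation). The p53 targets were higher, with 4 of 19 higher (7 adjusted over the list alone), Trp53inp1 among them (0.71 ± 0.1, adjusted p = 0.0176), and a median of 0.11 (adjusted p = 0.0168, adjusted p = 0.707 with an estimated correlation). Neuroectoderm was lower, with Gbx2 (−0.83 ± 0.12, adjusted p = 0.0176) among 3 lower of 16 (5 adjusted over the list alone) and a median of −0.19 (adjusted p = 0.0222, adjusted p = 0.707 with an estimated correlation). Cholesterol synthesis was higher, with 1 of 22 higher (4 adjusted over the list alone) and a median of 0.14 (adjusted p = 0.0261, adjusted p = 0.799 with an estimated correlation). Germline genes were higher, with Tex15 (0.93 ± 0.15, adjusted p = 0.0221) as the 1 call of 26 (1 adjusted over the list alone) and a median of 0.30 (adjusted p = 0.0328, adjusted p = 0.707 with an estimated correlation). The amino acid and ER stress response was lower with 0 of 22 called in edgeR (0 adjusted over the list alone) and a median of −0.17 (adjusted p = 0.0279, adjusted p = 0.791 with an estimated correlation). All of these but glycolysis and the amino acid response ceased to pass without DKO replicate 2 (adjusted p from 0.102 to 0.832), and the amino acid response without DKO replicate 1 (0.483). Germline did not pass without Pcgf5KO replicate 1 (0.0534) or 2 (0.0502), nor p53 without the first (0.0534) or cholesterol (0.0762) and amino acid response (0.0839) without the second. Tfcp2l1 (1.07 ± 0.08, adjusted p = 0.000702) and Tbx3 (2.45 ± 0.3, adjusted p = 0.0112) were higher in the pluripotency list, which did not pass and differed in the sign of median (−0.12) and mean (0.033). The feeder list did so too (0.011 and −0.216, adjusted p = 0.292).

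Between the single knockouts, with 8 libraries, Ranbp17 was at 406 ± 3.45 CPM in Pcgf3KO and 256 ± 1.71 in Pcgf5KO (−0.67 ± 0.09, adjusted p = 0.0268). Tfap2c (−0.89 ± 0.15, adjusted p = 0.0416), Nrp2 (−0.79 ± 0.12, adjusted p = 0.0385) and AU015836 (−0.79 ± 0.13, adjusted p = 0.0416) were also lower in Pcgf5KO, and Platr13 was the 1 gene higher. Without either of the Pcgf5KO replicates Platr13 alone passed (adjusted p of the others up to 0.525). With 7 libraries 14 were higher and 8 lower. Efhc2 rose from 2.27 to 14 ± 2.34 (2.63 ± 0.19, adjusted p = 0.000809), and the neighbours Ube2l6 (1.78 ± 0.14, adjusted p = 0.00145; chromosome 2, 84798828 to 84810335) and Smtnl1 (2.05 ± 0.19, adjusted p = 0.00297; chromosome 2, 84811176 to 84822652) were both higher in Pcgf5KO. Zfp990 (1.57) and Pnma5 (1.23) were higher too. Usp26 (−1.07 ± 0.09, adjusted p = 0.00154), Tfcp2l1 (−0.78 ± 0.08, adjusted p = 0.00427), Rhox6 (−1.35) and Gjb5 (−1.05) were lower. All but Efhc2 failed to pass with some library left out (adjusted p up to 0.761), and the counts were 924 and 985 without DKO replicate 1.

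Between the single knockouts 6 lists passed camera only. Each had 0 members called in edgeR with 7 libraries, although Tfap2c of the trophectoderm list was called with 8. Germline genes were lower in Pcgf5KO (26 genes, 6 lower adjusted over the list alone), with a median of −0.48 (adjusted p = 1.53e-09, adjusted p = 0.217 with an estimated correlation). Trophectoderm was lower (11 genes, 2 adjusted over the list alone), with −0.49 (adjusted p = 2.35e-05, adjusted p = 0.492 with an estimated correlation). Feeder markers were higher (23 genes, 1 adjusted over the list alone), with 0.26 (adjusted p = 0.000261, adjusted p = 0.327 with an estimated correlation). Wnt targets were higher (13 genes, 2 adjusted over the list alone), with 0.27 (adjusted p = 0.000261, adjusted p = 0.414 with an estimated correlation). Neuroectoderm was higher (16 genes, 2 adjusted over the list alone), with 0.28 (adjusted p = 0.000358, adjusted p = 0.327 with an estimated correlation). Primed epiblast was higher (13 genes, 5 higher and 1 lower adjusted over the list alone), with 0.15 (adjusted p = 0.0086, adjusted p = 0.327 with an estimated correlation). Tex11 (−1.27 ± 0.26, adjusted p = 0.153) and Tfap2c (−0.88, adjusted p = 0.0906) had the smallest p of the germline and trophectoderm lists. Primed epiblast did not pass without Pcgf3KO replicate 2 (0.0786).

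Gene families with more calls than their share were sought by symbol after the data were seen, over 244 stems. Collagens were lower against WT, with 8 of 35 called in Pcgf3KO (adjusted p = 2.62e-06), 5 in Pcgf5KO (0.0336) and 8 in DKO (5.44e-05). The feeder marker Col1a1 was called in all 3, Col1a2 and Col5a2 in Pcgf3KO and DKO. The feeder list (medians −0.81, −0.54 and −0.68) thus shares genes with the collagens. These were higher in DKO against Pcgf3KO (4, adjusted p = 0.0295) and in the interaction (7, adjusted p = 0.00055), with feeder marker Col5a1 in both. Keratins were lower in Pcgf5KO (4 of 15, adjusted p = 0.0223) and DKO (4, adjusted p = 0.00882), and in DKO against Pcgf3KO (4, adjusted p = 0.00148) together with annexins (4 of 11, adjusted p = 0.00074) and galectins (3 of 8, adjusted p = 0.00433).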

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

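The interaction, where the DKO differed from the sum of the single knockouts, was planned; the tests on the shared direction, the DKO libraries and the X chromosome were chosen only after those patterns had been seen, except that the prediction on unspliced RNA and the first on the genes that rose, which came out open, were written before their values. The values set apart here are those of the interaction test, a difference between groups.

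Of the 187 genes with an interaction in the 8-library test, 76 were called in both single knockouts in 1 direction and 46 in neither (180 and 262 of 594 with 7 libraries). With 8 libraries Bmp1 (2.82 ± 0.31, adjusted p = 0.000882), Csf1 (2.57 ± 0.33, adjusted p = 0.00203), Pmp22 (2.23 ± 0.34, adjusted p = 0.00367) and Asb4 (2.57 ± 0.65, adjusted p = 0.0387), lower in Pcgf3KO, had a positive interaction. Ptprtos (−2.73 ± 0.22, adjusted p = 0.000202), C78283 (−3.02 ± 0.31, adjusted p = 0.000483), Lemd1 (−2.67 ± 0.27, adjusted p = 0.000483), Apol6 (−3.59 ± 0.54, adjusted p = 0.0035) and Tnc (−3.61 ± 0.66, adjusted p = 0.0107) had a negative one, and of these Tnc did not pass in Pcgf3KO. With 7 libraries Hand1 (4.64 ± 0.64, adjusted p = 0.00821), Hmga2 (3.12 ± 0.35, adjusted p = 0.0033), Bmp1 (2.91) and Pcdh19 (2.75 ± 0.29, adjusted p = 0.00292) were positive. Gstp2 (−4.28 ± 0.32, adjusted p = 0.000845), As3mt (−3.27), C78283 (−3.10), Myo1g (−2.97) and Slfn9 (−2.86, adjusted p = 0.0476) were negative. In all 95 genes were positive and 92 negative of 2702 with 8 libraries, and 278 and 316 of 15669 with 7. Without Pcgf5KO replicate 2 the 8-library counts were 13 and 22, and without DKO replicate 2 370 and 423. Of the 10 genes that the naming rule gives with 8 libraries only Asb4 and Tnc did not pass with some library left out (adjusted p up to 0.197). With 7 libraries Hand1 (adjusted p = 0.0541 to 0.0756), Slfn9 (0.13 to 0.165), Bmp1 (0.0541) and As3mt (0.0523) did not pass without some replicate of a single knockout. The 7-library counts were 13 and 22 without Pcgf5KO replicate 1, and 2700 and 3012 without DKO replicate 2.

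Of the lists, 11 passed the interaction test. The p53 targets were positive, with 8 of 19 called (15 adjusted over the list alone) and a median of 0.70 (adjusted p = 6.51e-14, adjusted p = 0.0692 with an estimated correlation), led by Pmaip1 (1.45 ± 0.13, adjusted p = 0.00128) and Plk2 (1.79 ± 0.17, adjusted p = 0.00183). Endoderm was positive, with Col4a1 (2.16 ± 0.17, adjusted p = 0.00108) among 4 of 15 (6 adjusted over the list alone) and a median of 0.42 (adjusted p = 9.04e-06, adjusted p = 0.278 with an estimated correlation). Pluripotency was negative, with 2 positive and 6 negative of 24 (2 and 12 adjusted over the list alone) and a median of −0.41 (adjusted p = 2.87e-05, adjusted p = 0.246 with an estimated correlation). In it Dppa5a (−1.22 ± 0.14, adjusted p = 0.00396) and Pou5f1 (−0.58) lay opposite to Tbx3 (2.84). Glycolysis was negative, with 1 positive and 6 negative of 19 (2 and 13 adjusted over the list alone) and a median of −0.42 (adjusted p = 1.73e-06, adjusted p = 0.278 with an estimated correlation). Feeder markers were positive, with 7 positive and 1 negative of 23 (10 and 2 adjusted over the list alone) and a median of 0.95 (adjusted p = 0.000195, adjusted p = 0.278 with an estimated correlation), Mmp2 at 1.11 (adjusted p = 0.0111) and Tagln at −0.70 (adjusted p = 0.0574). Cholesterol synthesis was positive, with 3 of 22 (10 adjusted over the list alone) and a median of 0.33 (adjusted p = 3.07e-05, adjusted p = 0.443 with an estimated correlation). TGF-beta, Nodal and BMP signalling was positive (3 positive and 1 negative of 22, 6 and 2 adjusted over the list alone), with Lefty2 at 1.45 ± 0.12 (adjusted p = 0.00128) and a median of 0.23 (adjusted p = 0.00601, adjusted p = 0.278 with an estimated correlation). Hox (6 genes, 0 called in edgeR, 1 adjusted over the list alone) had a median of 1.57 (adjusted p = 0.0137, adjusted p = 0.278 with an estimated correlation). Polycomb-marked regulators (21 genes, 0 called in edgeR, 2 and 1 adjusted over the list alone) had 1.25 (adjusted p = 0.0139, adjusted p = 0.368 with an estimated correlation). Neuroectoderm (3 of 16, 5 and 2 adjusted over the list alone) had 0.60 (adjusted p = 0.0253, adjusted p = 0.278 with an estimated correlation). Imprinted genes (3 of 32, 4 adjusted over the list alone) had 0.17 (adjusted p = 0.0387, adjusted p = 0.278 with an estimated correlation), with Igf2 at 2.60 ± 0.29 (adjusted p = 0.0031). The TGF-beta, Hox, Polycomb-marked and neuroectoderm lists did not pass without DKO replicate 2. The imprinted list did not without Pcgf3KO replicate 1 or Pcgf5KO replicate 2. The positive p53 and feeder lists were lower in DKO than WT.

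All 187 interaction genes of the 8-library test had a sign opposite to both single effects, and 579 of 594 with 7 libraries did. This also held for 66.5% of all tested genes (58.2% in simulated unchanged groups), as the same WT libraries enter every term. Of the 187, 45 were called in DKO against WT. Simulated unchanged groups gave at most 2 interaction calls with 8 libraries and 7 with 7. A WT offset from all edited groups, by chance or not, moves the interaction and both single effects. The sign of a gene or list alone is thus no evidence of a shared pathway.

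The first pattern weighed is that the 3 knockout groups differed from WT in the same direction, and chance in the shared WT libraries alone is argued against, since the 8-library covariance was 0.169 between the single knockouts and 0.163 and 0.153 with DKO, and that of unchanged simulations at most 0.0457 (the 7-library correlations with DKO, 0.73 and 0.68, did not exceed the highest simulated ones, 0.74 and 0.71). A smaller share of feeder cells could account for part of the falls in the single knockouts, where the spread of the markers over their standard error was 2.3 against a bound of 3, while 6.09 in DKO argues against a uniform fall there (a measure chosen after the range of 2.07 in DKO, against a bound of 2, had left it open). For the genes that rose, the first test was open too, with a median of 1.15 against 1.95 for Tbx3, the highest pluripotency gene. The pluripotency median of at most 0.269, against a lower quartile of 0.83 for the genes higher in all 3, argues against a smaller feeder share as the whole rise, although this test was written after the first was seen, and those genes were selected for size and the list was not. Any difference between edited and unedited lines other than the genotype remains possible, as does an effect of the complexes themselves.

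The second pattern is that the DKO libraries differed from each other more than other replicates did. A trend on GC content likely accounts for part, since the difference correlated with GC content at −0.52, beyond −0.225 in the other groups. It is not the whole, as removing the trend took the SD from 0.309 to 0.253, still above 0.136. More unspliced RNA in DKO replicate 1 may add to it, since 14 of 14 genes lying within introns or unconfirmed were higher there, with a median of 0.74 against a bound of 0.122. Loss of the Y chromosome is argued against by a median of 0.31 for Ddx3y, Uty and Kdm5d, although Eif2s3y was at −3.19.

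The third pattern is that X-linked genes made up 8 of the 22 genes called between Pcgf5KO and Pcgf3KO with 7 libraries, 36.4% against 3.62% of tested genes. A chance draw is argued against by a Fisher exact test (p = 5.71e-07, or 8.8e-05 over all 154 pairs of chromosome and comparison), which treats genes as independent, although the X-linked share was 2 of 3 calls without Pcgf3KO replicate 1 and 84 of 1909 (4.4%) without DKO replicate 1. A different number of X chromosomes is argued against by the median of −0.027 over all X-linked genes. A single changed stretch is argued against as well, since the 8 genes lie in 7 stretches more than 1 Mb apart. Clone differences in silencing or a direct effect of Pcgf3 or Pcgf5 on these genes could each account for it, and neither was tested.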

How the results depend on the processing

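The 7-library test and the offset for GC content were chosen only after the data had been seen. No named gene's call was reversed in the alternatives run. Of the values of named genes under the alternatives, 1203 kept their side of the threshold in the 8-library test, 280 became weaker and 10 stronger. In the 7-library test they were 1572, 137 and 58. Of the values of lists, 1132 kept their side, 100 became weaker, 26 stronger and 2 reversed. The cause was not tested for any moved count below, unless the alternative's own construction gives it.

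The counts below are of genes higher and lower, and DKO-Pcgf3KO stands for DKO against Pcgf3KO, and so on. DESeq2 with 8 libraries called 87 and 63 in Pcgf3KO, 110 and 110 in Pcgf5KO and 117 and 93 in DKO against WT. It called 29 and 32 in DKO-Pcgf3KO, 102 and 113 in DKO-Pcgf5KO, 6 and 9 in Pcgf5KO-Pcgf3KO and 113 and 115 in the interaction. DESeq2 with 7 libraries called 195 and 199 in Pcgf3KO, 241 and 258 in Pcgf5KO and 232 and 284 in DKO against WT. There it called 149 and 222 in DKO-Pcgf3KO, 362 and 442 in DKO-Pcgf5KO, 41 and 38 in Pcgf5KO-Pcgf3KO and 288 and 362 in the interaction. DESeq2 ended the calls of Acsbg1 (adjusted p = 0.0995), Cyp1b1 (0.0699) and, with 7 libraries, Hand1 (0.0935) in Pcgf3KO, of Arhgap6 (0.104), Fthl17f (0.0973) and Rab32 (0.0756) in Pcgf5KO, and of Cyp1b1 (0.073) and Papln (0.0656) in DKO. RLE size factors and a filter of a CPM of at least 1 in at least 2 libraries kept every count within 1.5-fold, except that each called 2 genes higher in Pcgf5KO against Pcgf3KO with 8 libraries, where the planned test called 1. The CPM filter ended the calls of Acsbg1 in Pcgf3KO (adjusted p = 0.0548), Aire in Pcgf5KO (0.055) and Asb4 (0.0511) and Slfn9 (0.0571) in the interaction. RLE size factors changed 0 of the 140 list results.

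Without a filter on low counts the 8-library test called 147 and 132 in Pcgf3KO, 168 and 186 in Pcgf5KO and 202 and 171 in DKO against WT. It then called 111 and 107 in DKO-Pcgf3KO, 192 and 184 in DKO-Pcgf5KO, 17 and 29 in Pcgf5KO-Pcgf3KO and 213 and 205 in the interaction. Without that filter the 7-library test called 515 and 590 in Pcgf3KO, 580 and 642 in Pcgf5KO and 742 and 732 in DKO against WT. Between other groups it called 711 and 644 in DKO-Pcgf3KO, 1183 and 1129 in DKO-Pcgf5KO, 100 and 124 in Pcgf5KO-Pcgf3KO and 942 and 962 in the interaction.

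A test against a log2 fold change of 0.5 (glmTreat in edgeR), which asks for larger changes and so calls fewer genes by construction, gave with 8 libraries 15 and 7 in Pcgf3KO, 15 and 12 in Pcgf5KO and 22 and 13 in DKO against WT. Its 8-library counts were 1 and 0 in DKO-Pcgf3KO, 0 and 0 in DKO-Pcgf5KO, 1 and 0 in Pcgf5KO-Pcgf3KO and 7 and 11 in the interaction. With 7 libraries that test gave 36 and 35 in Pcgf3KO, 31 and 34 in Pcgf5KO and 48 and 54 in DKO against WT. Its 7-library counts were 11 and 5 in DKO-Pcgf3KO, 3 and 4 in DKO-Pcgf5KO, 7 and 1 in Pcgf5KO-Pcgf3KO and 50 and 51 in the interaction. The counts of 0 stand beside 480 genes at an unadjusted p of at most 0.05 in DKO against Pcgf3KO, 677 in DKO against Pcgf5KO and 237 in Pcgf5KO against Pcgf3KO in the edgeR test against 0.

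A fit of only the groups compared, which leaves fewer libraries to estimate the spread from, gave with 8 libraries 159 and 147 in Pcgf3KO, 249 and 254 in Pcgf5KO and 44 and 38 in DKO against WT. It gave for other pairs 1 and 0 in DKO-Pcgf3KO, 0 and 0 in DKO-Pcgf5KO and 124 and 143 in Pcgf5KO-Pcgf3KO. Such a fit gave with 7 libraries 1478 and 1552 in Pcgf3KO, 2457 and 2425 in Pcgf5KO and 154 and 175 in DKO against WT. For other pairs such a fit gave 15 and 20 in DKO-Pcgf3KO, 4 and 3 in DKO-Pcgf5KO and 907 and 967 in Pcgf5KO-Pcgf3KO. The direction of this shift followed the DKO libraries, whose chi-square per gene was 21.6: fits without them called more genes and fits with them fewer. With 8 libraries such a fit ended the calls of Cyp1b1 (adjusted p = 0.1), Papln (0.0748), Pcdhgb6 (0.0897) and Serpina3i (0.101) in DKO, and those of the genes named in DKO-Pcgf3KO other than Platr13 (0.245 to 0.315) and in DKO-Pcgf5KO (0.143 to 0.193). With 7 libraries it ended Igf2bp3 in DKO-Pcgf3KO (0.0899) and Hand1 (0.109), Otx2 (0.0879), Tmem88 (0.0879), Igf2bp3 (0.0657) and Pcdh19 (0.0657) in DKO-Pcgf5KO.

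The replicate number as a block gave with 8 libraries 110 and 91 in Pcgf3KO, 151 and 152 in Pcgf5KO and 174 and 138 in DKO against WT. The replicate block gave for other groups 34 and 31 in DKO-Pcgf3KO, 147 and 118 in DKO-Pcgf5KO, 4 and 8 in Pcgf5KO-Pcgf3KO and 165 and 155 in the interaction. With 7 libraries the block gave 205 and 211 in Pcgf3KO, 340 and 348 in Pcgf5KO and 204 and 289 in DKO against WT. For other groups the block gave 227 and 272 in DKO-Pcgf3KO, 708 and 824 in DKO-Pcgf5KO, 36 and 26 in Pcgf5KO-Pcgf3KO and 599 and 706 in the interaction. Residuals of libraries with the same number correlated between groups at −0.06 to 0.2, so pairing is not excluded. With the block, Hox in Pcgf3KO (adjusted p = 0.0726), primitive streak in Pcgf5KO (0.1) and neuroectoderm in the interaction (0.054) did not pass, and glycolysis passed in DKO (0.0366).

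The offset for GC content and transcript length gave with 7 libraries 443 and 456 in Pcgf3KO, 518 and 505 in Pcgf5KO and 514 and 636 in DKO against WT. Between other groups the offset gave 337 and 453 in DKO-Pcgf3KO, 389 and 629 in DKO-Pcgf5KO, 49 and 42 in Pcgf5KO-Pcgf3KO and 556 and 793 in the interaction. With it in place 167 of 170 and 199 of 200 calls in Pcgf3KO were kept, 196 of 205 and 255 of 263 in Pcgf5KO, and 207 of 209 and 296 of 296 in DKO.

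Each library was left out in turn, and the counts of the 8-library test moved widely. Pcgf3KO against WT ranged from 26 (without Pcgf3KO replicate 2) to 230 (without DKO replicate 1) higher, and from 12 (without Pcgf3KO replicate 1) to 207 (without DKO replicate 1) lower. Pcgf5KO against WT ranged from 19 (without Pcgf5KO replicate 2) to 334 (without DKO replicate 1) higher, and from 13 (without Pcgf5KO replicate 1) to 308 (without DKO replicate 2) lower. DKO against WT ranged from 29 higher and 31 lower (without WT replicate 1) to 385 and 379 (without DKO replicate 2). DKO against Pcgf3KO ranged from 1 higher and 0 lower (without Pcgf3KO replicate 1) to 291 and 355 (without DKO replicate 2). DKO against Pcgf5KO ranged from 0 higher and 0 lower (without Pcgf5KO replicate 1) to 418 and 404 (without DKO replicate 2). Pcgf5KO against Pcgf3KO ranged from 1 higher and 0 lower (without Pcgf3KO replicate 1) to 33 and 40 (without DKO replicate 1). The interaction ranged from 13 higher and 22 lower (without Pcgf5KO replicate 2) to 370 and 423 (without DKO replicate 2). The counts of 0 came from edgeR fits that lost a replicate of a single knockout.

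With 7 libraries, leaving out a DKO library raised every count. For Pcgf3KO against WT the range was from 27 higher and 19 lower (without Pcgf3KO replicate 1) to 1588 and 1579 (without DKO replicate 1). For Pcgf5KO against WT the range was from 18 higher and 19 lower (without Pcgf5KO replicate 1) to 2073 and 2046 (without DKO replicate 1). For DKO against WT the range was from 68 (without Pcgf5KO replicate 1) to 2644 (without DKO replicate 2) higher, and from 97 (without Pcgf5KO replicate 2) to 2735 (without DKO replicate 2) lower. For DKO against Pcgf3KO the range was from 4 higher and 3 lower (without Pcgf3KO replicate 2) to 2711 and 2860 (without DKO replicate 2). For DKO against Pcgf5KO the range was from 1 higher and 2 lower (without Pcgf5KO replicate 1) to 3233 and 3350 (without DKO replicate 2). For Pcgf5KO against Pcgf3KO the range was from 3 higher and 0 lower (without Pcgf3KO replicate 1) to 924 and 985 (without DKO replicate 1). For the interaction the range was from 13 higher and 22 lower (without Pcgf5KO replicate 1) to 2700 and 3012 (without DKO replicate 2).

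With an estimated inter-gene correlation 68 of the 140 list results became weaker and 0 passed, the lowest adjusted p being 0.0538. Of the lists 2 reversed: in DKO against Pcgf5KO without DKO replicate 1, primitive streak (adjusted p = 0.0157) and trophectoderm (0.00046) were higher in DKO, where with all libraries they were lower and did not pass. With other libraries left out their adjusted p reached 0.896 and 0.91. Without DKO replicate 1, endoderm (5.65e-05), cholesterol synthesis (5.36e-08), primitive streak (0.00349), feeder markers (0.00381), TGF-beta signalling (0.0197) and Hox (0.0257) passed in DKO against Pcgf3KO. Endoderm did so in DKO against Pcgf5KO (0.00361), and trophectoderm (5.97e-10) and primitive streak (3.36e-05) did in the interaction.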

Other observations

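The genes and libraries described here were chosen only after their values had been seen. Between the single knockouts, Xlr3a, an X-linked gene with close paralogs, was higher in Pcgf5KO (2.43 ± 0.29, adjusted p = 0.0144). The share of X-linked genes among the calls of the other 6 comparisons was 7% in Pcgf3KO, 5.8% in Pcgf5KO and 5.3% in DKO against WT, 5.9% in DKO against Pcgf3KO, 6.4% in DKO against Pcgf5KO and 5.4% in the interaction. Each was above the 3.62% of tested genes, with Fisher exact adjusted p of 0.0056 to 0.0492, but at least 0.246 over all 154 pairs.

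Some genes differed most between the 2 DKO libraries. The nuclear RNA Malat1 was at 283 CPM in DKO replicate 1 and between 75 and 115 in the other 6 full libraries. The metallothionein gene Mt1 (69.8 in replicate 1 and 166 in replicate 2) and Hand1 (16 and 46.4) were lower in DKO replicate 1.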
